A study of Mus musculus with 8 samples.

How the data were processed

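Liver RNA of 8 male C57BL/6 mice was sequenced, 1 library per mouse, on an Illumina NextSeq 500, per the labels. All mice received CL316243, an agonist of the β3-adrenergic receptor of adipocytes, and differed in the antagomiR (a chemically modified antisense inhibitor of a microRNA) given before it: 4 mice received antagomiR-122 and 4 received antagomiR-control. Groups and replicate numbers were taken from the sample titles. The table's columns were matched to the mice by group and number, and 0 columns of per-sample values stayed unmatched.

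Per the submitters' processing notes, reads were handled with bcl2fastq 2.15.0.4, cutadapt 1.7.1, TopHat2 2.0.13, Cufflinks 2.2.1 and Cuffdiff against GRCm38. The annotation release, the library kit's strand setting and the scaling between libraries are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to library size) for each mouse and each group. Their table also holds the authors' log2 fold change of the group values without a pseudocount, a Cuffdiff test statistic, which is a score with no fixed range, and the authors' p-value and q-value per gene. In the deposited table of all genes the fold change column was treated as a score, because 24 genes held sizes beyond 100, and it was used only for genes that Cuffdiff tested. A second deposited table holds 186 of the 188 genes that the authors called significant. The 2 left out had at most 0.383 FPKM in their larger group, and the lowest such value among those kept was 0.551.

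Of 43630 entries in the table, 43629 had values. GENCODE M21, on the same GRCm38 build, gave coordinates, exon lengths, 3' UTRs and names for 8673 of the 8988 genes that the table leaves unnamed. Depth was estimated from the low FPKM values: where whole fragments are counted, a gene's values are whole multiples of what 1 fragment is worth. With a separate step for each library, 92.5% of 2227 low values lay within 0.1 of a whole multiple of the gene's smallest value, against 19.3% with equal steps, on genes over 1500 bases with 1 annotated transcript. Steps between libraries were compared on values under 0.3 FPKM. FPKM are not counts, so no count test was run, and the depth bears on precision only through the counting error of low genes. Some zeros in the table may be failed estimates: Alb, Malat1 and mt-Rnr2 were listed at 0 in all 8 libraries, and 15 genes were listed at 0 in antagomiR-122 replicate 4 alone while above 5 FPKM in the other 7.

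Genes with a mean of at least 1 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (trend, robust, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes on this scale understate the change of low genes. Folds are ratios of mean FPKM. Gene lists were tested against all other tested genes with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists with more than 1 gene tested. The same lists were run with an estimated correlation and with fry. Members were also adjusted over their list alone, which does not correct for the number of lists. There were 40 lists, written before the data were examined: miR-122 targets, lipid and glucose metabolism, signalling, stress, clock, sex-biased, zonation, mitochondrial, ribosomal, nuclear and microRNA pathway genes, and 10 lists of markers of other cell types. Single values were compared with an exact two-sided permutation test, in which 4 mice against 4 reach at smallest p = 0.0286. Matches to the miR-122-5p seed (sites ACACTCC or CACTCCA, and ACACTCCA for an 8mer) were searched in the longest annotated 3' UTR of each gene, and mean log2 fold changes were compared by a permutation test with 100000 resamples. Interval bounds in that comparison cover the spread between genes, which are not independent replicates.

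The genes named in the text follow a rule written before the data were examined. It takes the 10 largest changes in each direction past the threshold with groups that do not overlap or, where none pass, the 5 smallest p in each direction. It adds Agpat1, Dgat1, Dgat2, up to 8 other miR-122 targets, the 2 to 4 members of each other list with the smallest p, and the miR-122 host transcript. Unnamed gene models are skipped, and some genes that the rule would name are not reported here. All other genes named in the text, in the closing tests too, were chosen after their values were seen. The scripts were tested on simulated data with the 11131 tested genes. limma recovered 28 of 67 genes changed 1.5-fold, 60 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 7 false calls. A shift of 0.4 log2 units put into the triglyceride synthesis list was recovered, with 0 of the other lists called. The simulated genes varied independently of each other, so this could not show false calls from list members that vary together. Simulated depths were also recovered, but those values were built from whole fragments with the same length error in each library. Their recovery was therefore fixed in advance and does not test depths estimated from Cufflinks FPKM.

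The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, array weights, the replicate number as a block, each mouse left out in turn, an adjusted p threshold of 0.1, 8mers only, adjustment of the seed comparison for 3' UTR length and expression, the authors' q, and their q under 0.01 with 1 FPKM in either group. Listed zeros of single libraries as missing values, and fry's test for change in either direction, were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.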

Results

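The livers of 8 male mice, 7 to 8 weeks old, were profiled by RNA-seq. Each mouse had received 5 µg of an antagomiR into the tail vein, then 1 mg/kg CL316243 under the skin 48 h later, and was killed 2 h after that. CL316243 stimulates fat cells to break down triglyceride and release fatty acids to the liver. The antagomiR was directed against miR-122, the most abundant microRNA of hepatocytes, in 4 mice and was a control oligonucleotide in the other 4. The comparison therefore asks which liver transcripts differ when antagomiR-122 is given before β3-adrenergic stimulation. Mice without CL316243 were not analysed here.

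Relative depth, estimated from the steps of the low FPKM values with a median of 1, was 0.941, 1.13, 0.914 and 1.01 in antagomiR-control replicates 1 to 4. It was 0.890, 0.993, 1.058 and 2.37 in antagomiR-122 replicates 1 to 4. Between 17774 and 18311 genes were above 0 in 7 libraries, and 18918 in antagomiR-122 replicate 4. That library also stood apart in the first principal component (32.4% of the variance), at 38.2 against -13.6 to 0.81 in the others. It listed 15 genes at 0 that were above 5 FPKM everywhere else, among them, chosen after their values were seen, mt-Co1, mt-Atp8, mt-Atp6, Serpina1b, Serpina1d and 9 Mup genes. Mitochondrially encoded genes made up 9.17% of its summed FPKM of 541058, against 20.4% to 24.1% in the others. That lower share includes the listed zeros of mt-Atp8 and mt-Co1, which averaged 82184 and 13657 FPKM in the other 7 libraries. In 9 other mitochondrial genes the median ratio to those 7 libraries was 1.03, so the share does not show a general loss of mitochondrial RNA. Without the 15 genes the first component took 23.8% of the variance, and this library lay at 14.9 against -21.7 to 8.78.

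**Figure D1:**
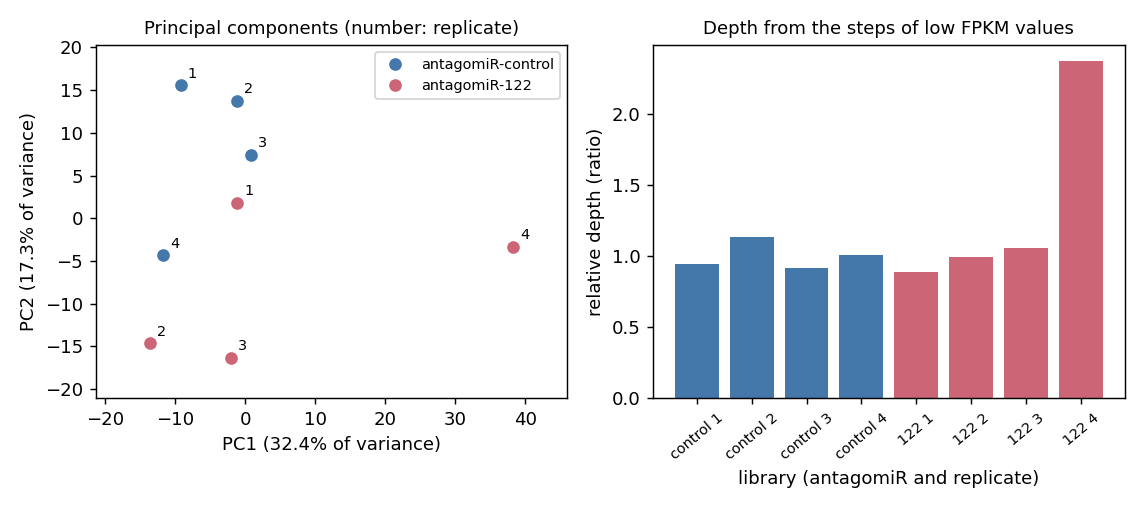
Left, the first and second principal components of log2(FPKM + 1) over tested genes, 1 point per mouse with its replicate number, blue for antagomiR-control and red for antagomiR-122; right, the relative depth of each library as a bar. AntagomiR-122 replicate 4 lies at 38.2 on the first component, and its relative depth is 2.37 against 0.89 to 1.13 in the other 7.

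The mature miR-122 was not measured by these libraries. The gene Mir122 was listed at 0 in all 8, and the authors' table holds an added miR-122 locus at chromosome 18, 65244001 to 65253000 on the plus strand of GRCm38. Its FPKM was 0.806, 0.626, 0.898 and 1.34 in antagomiR-control replicates 1 to 4, and 0.591, 1.17, 0.502 and 0.472 in antagomiR-122 replicates 1 to 4. The means were 0.918 ± 0.304 (SD, n = 4) and 0.683 ± 0.327 (SD, n = 4), and the groups overlapped (exact permutation test, two-sided p = 0.314). In the authors' deposited table this locus had p = 0.0125 and q = 0.343. An antagomiR acts on the mature microRNA, so the primary transcript does not measure the inhibition. Whether miR-122 was inhibited in these livers is therefore not shown by these data.

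Listed targets of miR-122 went both ways with antagomiR-122. Of 28 tested targets, 15 were higher and 13 lower, with a median log2 fold change of 0.01 (camera, Benjamini-Hochberg adjusted p = 0.878). Bckdk, the kinase of branched-chain ketoacid dehydrogenase, was at 5.78 ± 0.885 FPKM in controls and 8.44 ± 1.60 with antagomiR-122 (SD, n = 4 each), a log2 fold change of 0.47 ± 0.14 (SE). Klf6, a zinc finger transcription factor, differed the other way, at 6.40 ± 1.62 and 3.61 ± 0.635 FPKM, and so did Ppard, the nuclear receptor PPARδ, at 3.08 ± 0.789 and 1.93 ± 0.20 FPKM. In these 3 genes the groups did not overlap. Cidec, a lipid droplet protein, had a log2 fold change of 1.01 ± 0.42 with overlapping groups, and Slc35a4, Rell1, Ctdnep1 and Tmed3 had 0.28, -0.30, 0.19 and 0.28. None of the 28 passed the threshold, over all genes (limma, smallest adjusted p = 0.376) or adjusted over the list alone (smallest 0.0624).

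**Figure D2:**
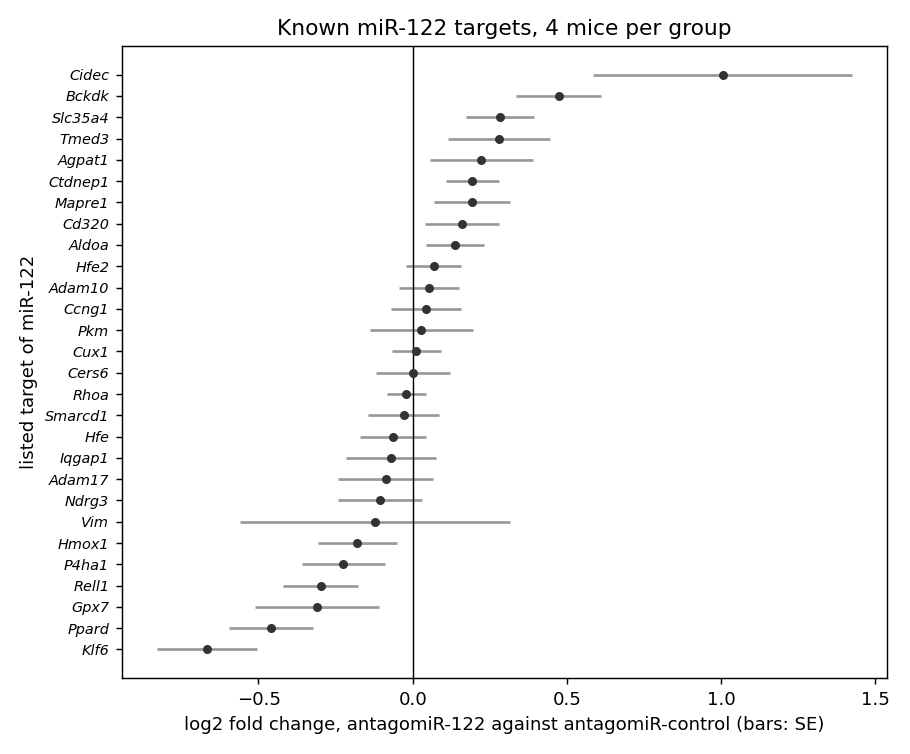
Log2 fold change of each tested miR-122 target, antagomiR-122 against antagomiR-control, with 4 mice per group, as points with bars of 1 SE; the vertical line marks 0. The 28 points spread to both sides, from Klf6 at -0.67 to Cidec at 1.01, with 15 above and 13 below 0.

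No enzyme of triglyceride synthesis passed limma's threshold, over all genes or adjusted over the list alone (smallest 0.653). This does not show that they were unchanged. Agpat1, which makes phosphatidic acid, was at 4.77 ± 0.574 FPKM in controls and 5.87 ± 1.696 with antagomiR-122. Dgat1, which catalyses the last step of the pathway, was at 15.6 ± 0.697 and 15.5 ± 1.84 FPKM, and Dgat2, the other enzyme of that step, at 203 ± 35.6 and 237 ± 56.3 FPKM (SD, n = 4 each). Their log2 fold changes were 0.22 ± 0.17, -0.02 ± 0.09 and 0.20 ± 0.18 (SE), with limma adjusted p of 0.7999, 0.976 and 0.838. Agpat9 and Ppap2c had 0.25 and 0.14. Of the 16 members tested, 9 were higher and 7 lower (camera adjusted p = 0.452).

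Genes with a miR-122 site in the 3' UTR were slightly lower than those without. The mean log2 fold change was -0.010 in 1625 tested genes with a seed match and 0.0041 in 8834 without, a difference of -0.0141 (95% interval -0.0233 to -0.0048; permutation test, two-sided p = 0.00512; camera p = 0.306). The interval and the permutation tests here cover the spread between genes and not between mice. In 18 of the 35 splits of the 8 mice into 4 and 4 the difference was as large, so chance is not excluded. The 322 genes with an 8mer differed by -0.0189 (permutation p = 0.0743). The median 3' UTR was 2308 bases with a site and 972 without. After the log2 fold changes were adjusted for 3' UTR length and mean expression, the difference turned to 0.0109 (permutation p = 0.0277). The sites were not part of that fit, and 9 of the 35 splits gave an adjusted difference as large. Without antagomiR-122 replicate 3 the unadjusted difference was -0.0017 (permutation p = 0.740) and without replicate 2 of that group -0.0023 (permutation p = 0.687). The 672 tested genes with no annotated 3' UTR were not searched.

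Across all genes, the transcripts with the smallest p included Nr1d1, Dbp and Cry2 on the higher side and Igfbp1 and Errfi1 on the lower side. Higher with antagomiR-122 were Nr1d1 (REV-ERBα, 24.1 ± 2.81 to 46.1 ± 9.64 FPKM, 1.92-fold), Dbp (2.26 ± 1.72 to 17.5 ± 6.00 FPKM, 7.74-fold) and Cry2 (3.64 ± 0.608 to 6.43 ± 0.817 FPKM, 1.77-fold), all components of the circadian clock. Cbx2, a Polycomb protein, went from 0.706 ± 0.0603 to 1.89 ± 0.517 FPKM, and Sphk2, a sphingosine kinase, from 8.74 ± 0.943 to 15.1 ± 1.87 FPKM. Lower were Igfbp1, an insulin-repressed binding protein of insulin-like growth factors (187 ± 46.5 to 61.0 ± 23.1 FPKM, a log2 fold change of -1.63 ± 0.26), and Errfi1, an inhibitor of the EGF receptor (499 ± 20.8 to 345 ± 29.6 FPKM). Irf2bp2, Lgalsl and Pigk were also lower, with log2 fold changes of -0.72, -0.68 and -0.40. In each of these 10 genes the groups did not overlap, with 4 mice in each. Sphk2 (chromosome 7, 45709467 to 45718002, minus strand) overlaps Dbp (45705088 to 45710155, plus strand), and without a known strand setting their reads cannot be told apart there.

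None of the 11131 tested genes passed the threshold: limma with Benjamini-Hochberg adjustment gave 0 genes, with a smallest adjusted p of 0.251, which all 10 genes above share. At an unadjusted p under 0.05 there were 828 genes, 419 higher and 409 lower, where 557 were to be expected by chance. The groups did not overlap in 503 genes, 4.52% of those tested, where chance gives 2.86%. On simulated data of this size limma recovered 89.6% of genes changed 2-fold and 41.8% of those changed 1.5-fold. The simulated genes varied independently of each other, so these shares may not hold for the real libraries. There, Dbp (7.74-fold higher) and Igfbp1 (3.06-fold lower), with groups apart, stayed at a limma adjusted p of 0.251. The 0 genes past the threshold therefore do not show that changes of 2-fold were absent.

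The authors' deposited table calls 188 genes significant among 13259 that Cuffdiff tested, 74 higher and 114 lower with antagomiR-122. Of these calls in the authors' deposited table, 169 were tested here, and all 169 had the same direction. The authors' group values are means of the same FPKM (over 1% apart in only 3 genes per group), so the shared direction was fixed in advance. In limma 125 of the 169 had an unadjusted p under 0.05, with a highest p of 0.372, and in 67 of the 169 (39.6%) the groups did not overlap. The calls were made on these same values, so these counts are not independent support. The following genes, chosen after their values were seen, are among the largest changes in calls of the authors' deposited table with groups apart. Higher were Trib3, a pseudokinase that binds AKT (0.974 ± 0.282 to 2.80 ± 1.064 FPKM), Gas1 (2.148-fold), Dact2 (1.97-fold), Sertad3 (1.92-fold), Clstn3 (1.89-fold), Pnldc1 (1.88-fold) and Pcsk4 (1.84-fold), besides Cbx2 and Nr1d1. Lower were Slc34a2, a phosphate transporter (5.68 ± 2.19 to 1.97 ± 0.376 FPKM), Gadd45g (52.7 ± 15.9 to 20.6 ± 8.21 FPKM), the cell cycle inhibitor Cdkn1a (40.5 ± 17.4 to 16.0 ± 6.67 FPKM) and the AP-1 subunit Jun (12.9 ± 4.62 to 6.66 ± 1.66 FPKM), with n = 4 mice each. Igfbp1 (3.06-fold), Fam222a (2.73-fold), Srrm4 (2.49-fold), Cldn14 (1.94-fold), Neu3 (1.91-fold) and Rnf144a (1.88-fold) were lower too. On the log2(FPKM + 1) scale, which understates the change of low genes, these were -1.63, -0.71, -0.87, -0.92, -0.50 and -0.66.

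Among the circadian clock genes, 6 of 17 rose and 2 fell when adjusted over the list alone (limma, Benjamini-Hochberg), and 0 passed over all genes. Nr1d1, Dbp, Cry2, Per3, Tef and Nr1d2 rose. Tef, Nr1d2, Arntl and Clock lie outside the naming rule and are named after their values were seen. Per3, a period gene, was at 0.905 ± 0.738 FPKM in controls and 2.92 ± 0.986 with antagomiR-122, Tef, a PAR bZIP factor related to Dbp, at 20.2 ± 7.94 and 39.3 ± 7.28, and Nr1d2 (REV-ERBβ) at 19.4 ± 4.48 and 27.5 ± 1.72. Arntl (BMAL1), at 5.92 ± 2.75 and 2.10 ± 0.994 FPKM, and its partner Clock, at 13.5 ± 1.54 and 9.34 ± 2.60 FPKM, fell (SD, n = 4 each). Npas2, a paralogue of Clock that lay under the filter and was picked after its values were seen, was at 1.33 ± 0.749 and 0.199 ± 0.141 FPKM (exact permutation test, two-sided p = 0.0286, the smallest possible). The list as a whole did not pass for a shift in 1 direction (camera adjusted p = 0.0948, and adjusted p = 0.806 with an estimated correlation). It passed camera without antagomiR-control replicate 2 (0.0237), without antagomiR-control replicate 3 (0.00653) and without antagomiR-122 replicate 2 (0.0165), in a range from 0.00653 to 0.159 over mice left out. For change in either direction, a test chosen after seeing the data, the list passed limma's fry (adjusted p = 0.0201), but not without antagomiR-control replicate 1 (0.0867), antagomiR-control replicate 2 (0.1002), antagomiR-122 replicate 1 (0.0768) or antagomiR-122 replicate 4 (0.0877), from 0.0138 to 0.1002 over mice left out. The labels give no time of day at which the mice were killed.

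**Figure D3:**
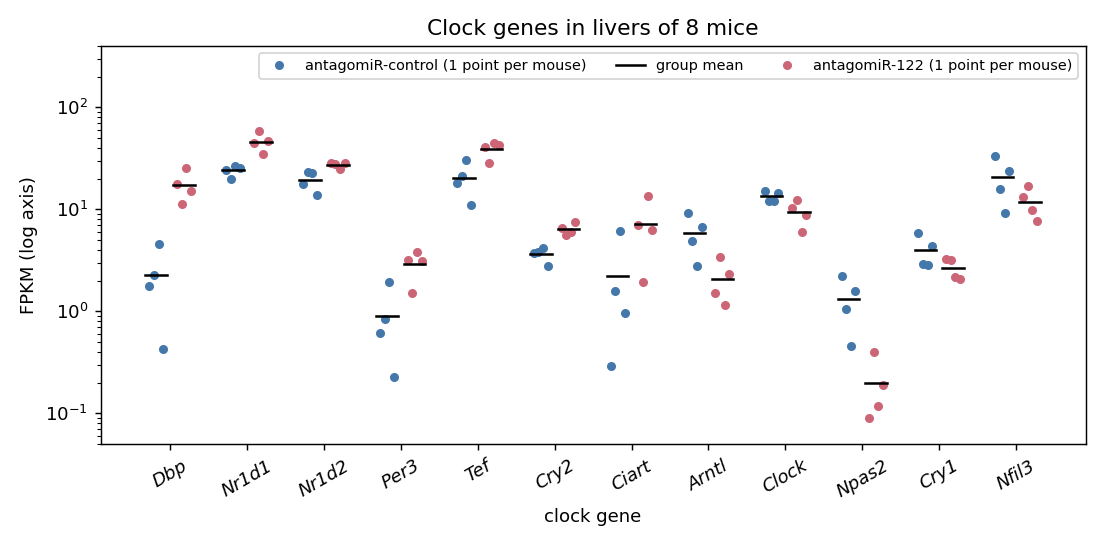
FPKM (log axis) of 12 clock genes in each of the 8 livers, 1 point per mouse, blue for antagomiR-control and red for antagomiR-122, with black lines at the group means. Dbp lies between 0.43 and 4.56 FPKM in controls and between 11.3 and 25.5 with antagomiR-122, and Npas2 between 0.455 and 2.21 and between 0.0898 and 0.401.

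Genes of fatty acid oxidation, ketogenesis and other PPARα targets were higher as a group, and genes of cholesterol synthesis and uptake were lower. In the first list 34 of 40 members were higher, with a median log2 fold change of 0.17 (camera adjusted p = 2.11e-05, lost with adjusted p = 0.806 with an estimated correlation). Acaa1a, a peroxisomal thiolase, went from 93.3 ± 6.88 to 123 ± 19.4 FPKM, Cpt1a, which admits fatty acids to mitochondria, from 117 ± 19.8 to 145 ± 5.802, and Bdh1, an enzyme of ketone body metabolism, from 98.6 ± 2.54 to 121.6 ± 18.3. Acot4 had a log2 fold change of 0.34. In the second list 21 of 25 members were lower, with a median of -0.21 (camera adjusted p = 0.00202, lost with adjusted p = 0.806 with an estimated correlation). The mevalonate pathway enzymes Mvd and Mvk went from 3.91 ± 0.28 to 2.62 ± 0.732 and from 8.65 ± 1.18 to 7.12 ± 0.752, while Lss had a log2 fold change of -0.22 (SD, n = 4 each). No member of either list passed alone, over all genes or adjusted over the list alone (limma, smallest 0.186 and 0.177). The cholesterol call was also lost without antagomiR-122 replicate 3 (camera adjusted p = 0.310, in a range from 9.51e-05 to 0.310 over mice left out).

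Male-biased liver genes were lower as a group, with 16 of 21 members below their control level and a median log2 fold change of -0.26 (camera adjusted p = 0.0149, lost with adjusted p = 0.806 with an estimated correlation). Gstp1, a glutathione transferase, fell from 1380 ± 227 to 884 ± 138 FPKM when adjusted over the list alone by limma (Benjamini-Hochberg adjusted 0.0283, and 0.308 over all genes). Mup20, a urinary protein, was at 4770 ± 1494 and 3058 ± 984 FPKM, Elovl3 at 454 ± 156 and 304 ± 207, and Hsd3b5 at 32.2 ± 10.7 and 22.4 ± 11.2 (SD, n = 4 each). The list's call was also lost without antagomiR-control replicate 1 (0.0825), antagomiR-control replicate 4 (0.262), antagomiR-122 replicate 1 (0.0927) or antagomiR-122 replicate 4 (0.444), in a range from 1.37e-06 over mice left out, and 3 members, Mup1, Mup7 and Mup12, are among those listed at 0 in antagomiR-122 replicate 4. Female-biased genes, with 11 of 12 members higher, did not pass (camera adjusted p = 0.105), and Acot3 and Cyp2b9 had log2 fold changes of 0.49 and 0.85.

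In glucose metabolism, single genes differed more than the lists. Igfbp1 and Gadd45g, of the gluconeogenesis and cAMP response list, were lower when adjusted over the list alone (limma, 0.00239 and 0.0296). Over all genes they did not pass (limma adjusted p = 0.251 and 0.423). The list with 10 of 15 members lower did not pass (camera adjusted p = 0.105), and Sik1 and Fbp1 had log2 fold changes of -0.49 and 0.28. The glycolysis and glycogen list, with 12 members higher and 11 lower, did not pass (camera adjusted p = 0.646), and Gys2, the liver glycogen synthase, and Eno1, an enolase, had 0.42 and 0.26. Adjusted over that list alone, 1 member, not named here, was lower (limma, 0.0312), and 0 were higher. Trib3, a member of both the insulin signalling and the ER stress and amino acid response list, was higher adjusted over each alone (limma, 0.0268 and 0.0426). Both values come from the same test of 1 gene, which did not pass over all genes (limma adjusted p = 0.321). Neither list passed (camera adjusted p = 0.550 and 0.452), and in both the median was just under 0 (-0.0064 and -0.0067) while the mean (0.066 and 0.11) and the test lay above. Foxo3, Mtor and Foxo1 had log2 fold changes of 0.37, 0.33 and -0.28, and Sesn2, Nupr1 and Asns had 0.39, 0.41 and 0.62.

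The other lipid and bile lists did not pass camera's threshold. Fatty acid synthesis and desaturation had 13 of 19 members higher (adjusted p = 0.266), with Elovl6 at a log2 fold change of 0.41 and Slc25a1 at 0.14. Lipid droplet and lipolysis had 11 of 18 higher (0.292), with Lipe, the hormone-sensitive lipase, at 5.11 ± 0.226 and 6.67 ± 1.09 FPKM (SD, n = 4 each). Lipoprotein assembly and clearance had 17 of 22 higher (0.114), with Abca1 at -0.23 and Sar1b at 0.15. Bile acid synthesis and transport had 10 of 19 higher (0.595), with Nr0b2, the repressor SHP, at 0.56 and Abcc3 at 0.20. Xenobiotic metabolism had 21 of 28 higher (0.105), with Nr1i3, the nuclear receptor CAR, at 42.7 ± 2.44 and 52.7 ± 3.02 FPKM and Cyp2c54 at 0.27.

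Stress, inflammation and growth lists did not pass either (camera). Immediate early and heat shock genes were lower in 14 of 20 (adjusted p = 0.105), with Jun at -0.83 and Ier2 at 0.30. The cell cycle list was lower in 10 of 15 (0.105), where Cdk1, Mcm3 and Ccna2 had -0.78, 0.29 and -0.35. Mcm6, a replication helicase subunit, was at 2.96 ± 0.336 and 1.77 ± 0.389 FPKM. Its limma adjusted p was 0.0252 over the list alone and 0.321 over all genes. The p53 and growth arrest list split evenly, with 7 members higher and 7 lower (0.700), a median of 0.0017 and a mean of -0.051. Interferon response genes were higher in 18 of 29 (0.594; Oasl1 0.34, Ddx58 -0.16), acute phase and inflammation genes in 13 of 29 (0.700; Cxcl1 -1.13, Itih4 0.23), and iron handling genes in 12 of 20 (0.700; Smad7 0.46, Atoh8 0.40). The microRNA pathway list was higher in 5 of 15 (0.407; Tnrc6b -0.32, Rora -0.33).

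Hepatocyte identity, zonation and RNA quality lists did not pass (camera). The hepatocyte secreted and identity list had 13 of 19 members higher (adjusted p = 0.267). Its member Cebpa, a transcription factor of hepatocyte differentiation, was at 63.2 ± 9.52 and 95.5 ± 9.07 FPKM (limma adjusted p = 0.00759 over the list alone and 0.288 over all genes). Foxa3, Serpina1c and Ambp of that list had -0.22, 0.16 and -0.14. Pericentral genes were higher in 13 of 16 (0.105; Cyp2e1 0.29, Ang 0.30) and periportal genes in 6 of 17 (0.878; Asl 0.23), the latter with a median of -0.020 and a mean of 0.0090. Fetal liver and oncofetal genes were higher in 3 of 5 (0.783; Sox9 -0.37, Mycl 0.41), with a median of 0.053, a mean of 0.0080 and a test that lay below 0. Ribosomal protein genes were higher in 25 of 28 (0.266; Rpl18 0.14, Rpl10 0.09), and nuclear and RNA quality transcripts in 4 of 5 (0.266; Hist1h1c 0.38, Hist1h4h 0.29). Mitochondrially encoded genes were higher in 8 of 13 (0.783; mt-Nd6 0.23, mt-Nd5 0.17), with a median of 0.05 and a test above 0, and a mean of -0.61 that includes the 3 genes listed at 0 in antagomiR-122 replicate 4.

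No list of markers of other liver cell types passed with all 8 mice (camera). They were lower in 14 of 16 for stellate cells and fibroblasts (adjusted p = 0.105; Lrat -0.37, Rgs5 -0.16), 11 of 15 for sinusoidal endothelial cells (0.159; Lyve1 -0.37, Bmp2 -0.16), 10 of 14 for Kupffer cells (0.460; Timd4 -0.14, Slc40a1 -0.16) and 6 of 9 for monocytes and neutrophils (0.168; S100a9 -0.66, S100a8 -0.70). B and dendritic cell markers were higher in 4 of 5 (0.243; H2-Ab1 0.39, H2-Aa 0.36) and erythroid markers in 5 of 6 (0.460; Hba-a2 0.28, Hba-a1 0.24). Of 3 T and NK cell markers, Cd4 had -0.74 and Ccl5 0.68 (0.851), with a median of 0.0030 and a mean of -0.021. Of 3 cholangiocyte markers (0.115), Spp1, osteopontin, was at 31.5 ± 3.38 and 25.8 ± 1.35 FPKM. Its limma adjusted p was 0.0389 over these 3 genes alone and 0.536 over all genes. Both adipocyte markers tested were lower (0.170; Fabp4 -0.22, Car3 -0.18), and of the pancreas and gut markers only Cela1 was tested, at 0.05. Leaving out 1 mouse made some of these lists pass: stellate (0.0293 without antagomiR-control replicate 3, 0.0442 without antagomiR-122 replicate 1 and 0.00871 without antagomiR-122 replicate 3), Kupffer and cholangiocyte (0.0354 and 0.0254 without antagomiR-control replicate 3), monocyte and neutrophil (0.0201 without antagomiR-control replicate 4 and 0.0373 without antagomiR-122 replicate 3), sinusoidal (0.0470 without antagomiR-122 replicate 4), B and dendritic cell (0.0415 without antagomiR-122 replicate 2) and adipocyte (0.0373 without antagomiR-122 replicate 3).

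**Figure D4:**
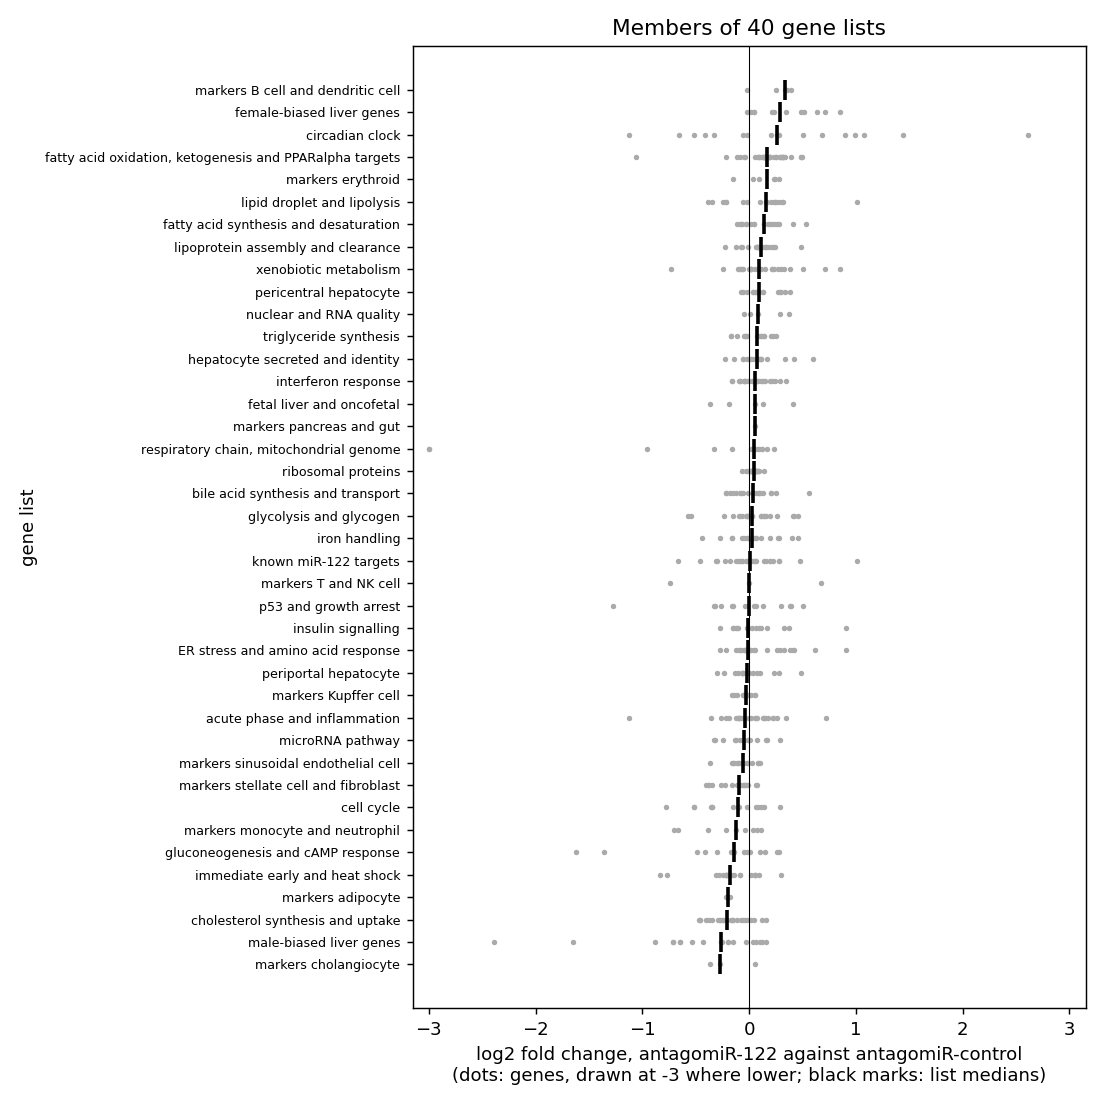
Log2 fold change, antagomiR-122 against antagomiR-control with 4 mice per group, of each tested member (grey dots) of the 40 gene lists, with a black mark at each list's median and values under -3 drawn at -3. Medians run from -0.27 for cholangiocyte markers to 0.33 for B and dendritic cell markers; that of fatty acid oxidation is 0.17 and that of cholesterol synthesis -0.21.

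Of the 39 lists tested with camera, 3 passed, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.806, or with fry, where it was 0.638. The number past camera's threshold moved to 7 without antagomiR-control replicate 2, 12 without antagomiR-control replicate 3, 9 without antagomiR-122 replicate 2, 7 without antagomiR-122 replicate 3 and 6 without antagomiR-122 replicate 4. Besides the clock and cell type marker lists, these lists were added, each with its camera adjusted p. Leaving out antagomiR-122 replicate 1 brought in cell cycle (0.0479). Without antagomiR-122 replicate 2 the added lists were xenobiotic (0.0165), female-biased (0.0057), immediate early (0.0165) and pericentral (0.0419). With antagomiR-122 replicate 3 left out they were cell cycle (0.019) and immediate early (0.019). Leaving out antagomiR-122 replicate 4 brought in interferon (0.047), xenobiotic (0.047) and ribosomal (0.000419). Without antagomiR-control replicate 1 the added list was gluconeogenesis (0.00804). With antagomiR-control replicate 2 left out they were fatty acid synthesis (0.0214), xenobiotic (0.0211) and immediate early (0.0214). Leaving out antagomiR-control replicate 3 brought in xenobiotic (0.00168), female-biased (0.0254), cell cycle (0.0354), immediate early (0.0354) and pericentral (0.0403).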

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

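The comparison of each mouse with the other 3 of its group was fixed beforehand, and the tests of explanations and the other splits of the mice in this part were chosen only after the results were seen, as were the genes Tef, Nr1d2, Arntl, Clock, Ciart, Cry1, Nfil3, Trf, Apoe, mt-Co1 and mt-Atp8.

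Single mice lay far from the other 3 of their group in genes such as Elovl3, a fatty acid elongase, and Hba-a1, a globin. In antagomiR-122 replicate 2, Elovl3 was at 611 FPKM (others 180 to 244), Hsd3b5 at 38.9 (15.2 to 19.3), Asl at 201 (333 to 353), Lrat at 3.01 (3.69 to 3.79) and S100a8 at 2.42 (5.46 to 6.08). In antagomiR-122 replicate 3, Hba-a1 was at 71.8 (42.0 to 46.8) and Hba-a2 at 52.4 (28.8 to 30.1). In antagomiR-122 replicate 1, Ier2 was at 4.84 (7.23 to 7.36) and S100a9 at 6.35 (2.98 to 3.47). In antagomiR-122 replicate 4, Acot3 was at 7.99 (20.98 to 22.7), Spp1 at 23.8 (26.3 to 26.6) and Timd4 at 7.11 (5.69 to 5.801), relative depth was 2.37 (0.890 to 1.058) and 18918 genes were above 0 (17774 to 17896).

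Control mice with a far value were the following. Replicate 1 had Acot4 at 5.60 FPKM (others 4.61 to 4.75), Jun at 19.7 (9.99 to 11.5) and Slc25a1 at 97.3 (112 to 114). Replicate 2 had Ddx58 at 8.82 (9.88 to 9.97) and Serpina1c at 1422 (1182 to 1208). Replicate 3 had Agpat9 at 13.3 (8.75 to 9.22), Ambp at 1525 (1724 to 1764) and Atoh8 at 3.21 (1.98 to 2.11). Replicate 4 had Cbx2 at 0.616 (0.727 to 0.745) and Rpl18 at 274.95 (223 to 232). In all, 24 of 248 groups of 4 held such a mouse, by the 95% critical value of Dixon's ratio, where chance gives about 12.4, and 5 of the 24 were antagomiR-122 replicate 4.

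The circadian clock genes Nr1d1, Dbp, Cry2, Per3, Tef and Nr1d2 were higher and Arntl and Clock lower with antagomiR-122. Of the 35 splits of the 8 mice into 4 and 4, 2 gave at least as many clock genes past the threshold over the list alone, with 8 in the real split and 9 at most in another, the one that swaps antagomiR-control replicate 3 with antagomiR-122 replicate 2, so chance is not excluded. Release of these transcripts from miR-122 is argued against for the 6 higher genes, since 0 of the 6 hold a site in the 3' UTR searched, against 15.5% of tested genes. Within the groups, the mean of Dbp, Nr1d1, Nr1d2, Per3, Tef, Cry2 and Ciart moved against that of Arntl, Clock, Cry1 and Nfil3 (r = -0.861 over the 8 mice, exact permutation p = 0.0208), as it would if mice differed in clock phase. This holds for the means and not for each member. In antagomiR-122 replicate 2, Nr1d1 deviated from its group mean by 0.35 log2 units, with Arntl (0.56) and against Dbp (-0.53). In antagomiR-122 replicate 3 the deviations of Nr1d1, Arntl and Dbp were -0.37, -0.47 and 0.58. In antagomiR-control replicate 3 Nr1d1 (0.13) went with Dbp (0.93) and against Arntl (-0.78). Times of killing are not given in the sources used here, so a difference in time of day between the groups and an action of antagomiR-122 on the clock cannot be told apart.

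Mitochondrial and secreted protein genes made up most of the 15 genes listed at 0 in antagomiR-122 replicate 4 alone. A loss of mitochondrial transcripts in that mouse is argued against by 9 other mitochondrial genes, whose median ratio to the other 7 libraries was 1.03 (0.774 to 1.26). A limit on fragments per single gene in this deepest library is argued against only for genes above 0 elsewhere. Of the 20 genes with the most expected fragments, 18 were above 0, Trf and Apoe among them, and only mt-Co1 and mt-Atp8 at 0. Expected fragments were taken from the other 7 libraries, so genes listed at 0 in every library could not enter that count. For those genes, and for a limit per genomic region, it cannot decide. For 14 of the 15 genes, expected fragments were summed within 500 kb, and these regions ranked at a median percentile of 95.0 (lowest 62.5). Those 9 other mitochondrial genes share a region with mt-Co1 and were above 0, which argues against a limit on the whole of that region. They do not bear on the regions of the Mup and Serpina1 genes, for which a limit per region stays open. Failed estimates in families of near-identical genes may account for 11 of the 15, which are Mup and Serpina1 genes, but nothing in the tables decides this.

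The shifts of the fatty acid oxidation, cholesterol and male-biased lists were matched or exceeded in several other splits of the 8 mice. In 9 of the 35 splits the fatty acid oxidation list had a camera p as small as the real 5.41e-07 (smallest other 1.67e-15), in 14 of 35 the cholesterol list (0.000104, smallest other 1.15e-10) and in 15 of 35 the male-biased list (0.00114, smallest other 5.67e-20), so chance is not excluded for any of the 3. The number of lists past the threshold was 3, and 33 of the 35 splits gave as many, up to 16. This may come from a structure among the mice or from members that vary together more than camera's preset allows (estimated correlations of 0.49, 0.58 and 0.67 for the 3 lists), and both stay open. The deepest library as the cause of the fatty acid oxidation shift is argued against, since without it the camera adjusted p was 1.77e-10 (0.0320 at most over mice left out). An effect of miR-122 inhibition on these lists stays open.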

How the results depend on the processing

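Listed zeros of single libraries as missing values, and fry in either direction, were chosen only after the results were seen. The DESeq2 alternative was not run, because the values are FPKM and not counts.

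No gene passed limma's adjusted threshold under any alternative (0 genes, also at 0.1), while the authors' Cuffdiff q called 188, or 132 at q under 0.01 with 1 FPKM. The count at an unadjusted p under 0.05, 828, was 1296 with no filter and 531 with a mean of at least 5 FPKM (fewer genes tested), and 603 to 978 without single mice. With replicate numbers as a block (replicate block) it was 660, with 0 genes and 3 lists past. Numbers do not pair the mice: deviations from the group means correlated at 0.13, -0.24, -0.06 and -0.18.

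Lists past camera's threshold, 3, were 6 with no filter, 5 with a mean of at least 5 FPKM, 0 with an estimated correlation and 0 with fry, and 3 to 12 without single mice. The estimated correlation gave 0.806 for the fatty acid oxidation, cholesterol and male-biased lists, and fry 0.638, 0.759 and 0.759. Both take the members' own correlation into account, but whether that alone lost the calls was not tested. Without single mice the adjusted p ran from 1.77e-10 to 0.0320 for fatty acid oxidation, 9.51e-05 to 0.310 for cholesterol and 1.37e-06 to 0.444 for male-biased genes. It ran from 0.00653 to 0.159 for the clock list, which reached 0.0377 with a mean of at least 5 FPKM. For known miR-122 targets it ran from 0.437 to 0.999, and for triglyceride synthesis from 0.184 to 0.947. Clock genes past the list-alone threshold numbered 6 to 11. The cause of the other changes was not tested either.

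The seed match difference was -0.0189 with 8mers only and reversed to 0.0109 with 3' UTR length and expression adjusted. Unadjusted, it ran from -0.0268 to -0.0017 without single mice. Of 1987 settings of the 119 named genes 0 passed, and 7 changed sign, in Dgat1 and Cela1. In the 33 other lists, of 625 settings 34 passed, 0 reversed, 46 changed sign without a call and 545 stayed the same. Counting error adds to the spread of genes near 1 FPKM most.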

Other observations

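The tests on other splits of the mice in this part, and fry in either direction, were chosen only after the results were seen.

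Genes of the p53 and growth arrest list went both ways with antagomiR-122. Cdkn1a (log2 fold change -1.28), Mdm2 (-0.26), Gadd45b (-0.32) and Ei24 (-0.15) were lower, and Bbc3 (0.50), Gadd45a (0.39), Sesn2 (0.39) and Sesn1 (0.30) higher, each at an unadjusted limma p under 0.05, and none passed over all genes; Gadd45b, Ei24, Bbc3, Gadd45a and Sesn1 were chosen after their values were seen. The list was picked as the smallest of 39 by limma's fry in either direction (adjusted p = 9.05e-06, and 1.47e-05 to 0.00147 without single mice, and 0.0313 with replicate numbers as a block). At an unadjusted limma p under 0.05 were 8 of 14 members, against at most 3 in any other of the 35 splits (1 of 35 as many). The smallest p of any list in each split was as small as the real 2.32e-07 in 1 of the 35 (fry, smallest other 7.83e-05). The list and the test were both picked on these data, so neither count excludes chance.

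The clock and gluconeogenesis lists also passed limma's fry in either direction (adjusted p = 0.0201 each), and each p, 0.00122 and 0.00155, was the smallest of the 35 splits (1 of 35 each, smallest other 0.00172 and 0.00481), with the same limit. With replicate numbers as a block they were at 0.0883 and 0.0644, and without antagomiR-control replicate 2 at 0.1002 and 0.207, which left 1 list past, the p53 list. Without antagomiR-122 replicate 1 both were at 0.0768, and without antagomiR-122 replicate 4 at 0.0877 and 0.167. The clock list was at 0.0867 without antagomiR-control replicate 1, and the gluconeogenesis list at 0.365 without antagomiR-122 replicate 3. Without antagomiR-122 replicate 2, 5 lists passed. As many lists as the real 3 passed in 4 of the 35 splits, with 9 at most in another, so chance is not excluded for the number.

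Genes with a miR-122 site differed by -0.0141 in mean log2 fold change from genes without, and 18 of the 35 splits gave a difference as large, up to 0.0454. After adjustment for 3' UTR length and expression the difference was 0.0109, with 9 of 35 splits as large, up to 0.0155. Chance is not excluded for either.

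The number of genes at an unadjusted limma p under 0.05, among them Sphk2, Errfi1 and Nr1d1, was 828. In 7 of the 35 splits it was as large, up to 1248, so chance is not excluded for the number.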
